A study of Arabidopsis thaliana with 12 samples.

How the data were processed

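Gene expression was measured in early embryos of Arabidopsis thaliana, accession Col-0, on Affymetrix ATH1 arrays, which measure targeted transcripts with probe sets of short oligonucleotides, several for some genes. The 12 arrays fall into 4 groups of 3. Nuclei of the proembryo, of the suspensor and of the whole embryo came from embryos of 2 to 16 cells; per the labels' protocols, ovules were fixed in paraformaldehyde, nuclei carrying tissue-specific markers were isolated by flow cytometry, and RNA was released in a buffer with proteinase K. The fourth group is cellular RNA of whole embryos of 8 to 32 cells, squeezed out of the ovules, washed, and extracted with a PicoPure kit. Per the labels, plants grew in long days of 16 h light and 8 h dark, and all RNA went through the same single-round amplification and biotin labelling. Stage, fixation and extraction differ together with cells against nuclei and cannot be told apart from it. The titles number the replicates and call them biological, without saying whether that means separate plants, harvests or sorts, and p-values measure the spread between these samples.

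The deposited values are linear intensity values, 1 per probe set and array. Per the submitters' processing notes the tools were MAS5 and affy 1.32.1, with no role or order given; background, summarisation and any later step are not given in the sources used here. In the values themselves, the mean after trimming 2% from each end of the 22810 probe sets was 200.02 on every array, so the authors' scaling was kept and nothing was rescaled. The number of arrays, 3 per group, limits the precision of every value.

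Probe sets were named from the platform's probe annotation, with symbols updated through NCBI gene identifiers from a table of assembly TAIR10.1, used for names only. Of the 22746 non-control probe sets, 13513 had 1 gene, 503 had several and 8730 are unnamed here; 13436 matched a gene identifier and 77 did not. A symbol other than the locus tag was present for 1580. Of the lineage markers that were to be named in any case, WOX8, WOX2, ARF13, IAA10, WOX9, ATML1, PIN7 and DRN, also called ESR1, have no named probe set here, and another is not reported here. A named probe set was present for 18 of the 186 genes listed individually in the gene lists. No level is given for the others.

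The unit of analysis was log2(intensity + 16). The 64 control probe sets were left out, and a probe set was kept if it lay above its own array's median (the 50th percentile) in at least 3 arrays of the fit. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend), with Benjamini-Hochberg adjustment over the probe sets kept and a threshold of 0.05. The 3 comparisons among nuclei shared a fit of 9 arrays, and cells were compared with whole-embryo nuclei in a fit of those 6 arrays. Log2 differences are on the log2(intensity + 16) scale, which understates changes of dim genes. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for names and plots.

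Gene lists were tested with camera (preset correlation 0.01), with an estimated correlation and with fry beside it, over the brightest probe set of each gene, for lists with at least 3 measured genes. Of the lists fixed before the data were examined, 6 could be tested: mitochondrion-encoded genes, plastid-encoded genes, histones, nuclear-encoded photosystem proteins, expansins with xyloglucan endotransglucosylases, and sugar and amino acid transporters. Further lists were built from symbols in the annotation before any comparison was run, which made 30 tested lists in the comparisons among nuclei and 29 in cells against nuclei; adjusted p-values are given over the fixed lists and, where named so, over all lists.

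The tests, the comparisons, the fixed lists, most alternatives and the rule for naming genes were set before the data were examined. For suspensor against proembryo and for cells against nuclei, the rule takes the 10 largest differences in each direction among probe sets past the threshold with a symbol other than the locus tag, no overlap between the arrays of the groups and no organelle gene, and in each fixed list the 3 members with the smallest p and any past the threshold over the list alone, up to 4. For the other comparisons it takes the 5 largest in each direction, or, where none passes, the 3 with the smallest p. Reading the clause on list members as covering only the first pair of comparisons was settled after results under the alternatives had been seen. Genes known only by a locus tag were chosen after their values were seen.

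Array quality was compared by exact two-sided permutation tests, which cannot give a p under 0.1 with 3 arrays against 3. The procedure was tested on simulated data with 50 changed probe sets at each of several sizes: for suspensor against proembryo nuclei 32% of changes of 1 log2 unit and 68% of changes of 2 were recovered among 12848 probe sets, with 4 false calls. For proembryo against whole-embryo nuclei these shares were 18% and 76% among 12814, with 9 false calls. For cells against nuclei they were 28% and 86% among 11687, with 9 false calls. The simulated values were independent normal draws, without correlation between genes, array effects or a spread that differs between groups. The shares and false calls hold for such data only. Alternatives covered the pseudocount, the filter, normalization between arrays, the arrays in the fit, the prior, array weights, the replicate number as a block and leaving out each array. A fit with the level of the hybridisation controls as a covariate was added after seeing the data.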

Results

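The arrays profile the embryo at the stage when its lineages have just parted: the proembryo, which forms most of the plant, and the suspensor, the short file of cells that joins it to the mother tissue. There were 3 arrays each of proembryo nuclei, suspensor nuclei, whole-embryo nuclei and whole-embryo cells. Over 13474 probe sets, the first principal component held 31.2% of the variance and separated the cells (60.43 ± 22.9, SD, n = 3) from whole-embryo nuclei (-13.31 ± 10.3, SD, n = 3). Suspensor nuclei lay apart from the other nuclei on the next component (16.3% of the variance), between -64.77 and -3.82, while proembryo nuclei lay between 21.22 and 31.06. The cell arrays, between -17.43 and -3.81, overlapped the suspensor range there. Proembryo and whole-embryo nuclei correlated across probe sets at 0.882 to 0.95, as high as replicates within those groups (0.879 to 0.92). Suspensor and proembryo nuclei correlated at 0.795 to 0.91 and suspensor replicates with each other at 0.843 to 0.885. Suspensor replicate 1 correlated more closely with proembryo replicate 1 (0.91) than with the other suspensor arrays (0.885 and 0.847).

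Signs of RNA amount and quality differed between arrays. The hybridisation controls, added in fixed amount, averaged 12.75 ± 1.26 log2 units (SD, n = 3) in suspensor nuclei, from 11.39 to 13.88, against 12.14 ± 0.493 in proembryo nuclei, 12.36 ± 0.561 in whole-embryo nuclei and 11.65 ± 0.149 in whole-embryo cells. On the second principal component the suspensor arrays lay in the order of these levels: replicate 1 (11.39) at -3.82, replicate 2 (12.99) at -29.89 and replicate 3 (13.88) at -64.77. Whether the control level underlies their spread on that component was not tested. The difference in control level between cells and whole-embryo nuclei had an exact permutation p of 0.1, the smallest these group sizes allow. The 25S ribosomal RNA probe set read 9514 ± 1160 intensity units in cells and 22150 ± 1940 in whole-embryo nuclei (SD, n = 3; exact permutation p = 0.1). The log2 ratio of 3' to 5' actin signal was 3.59 ± 0.259 in suspensor nuclei and 4.57 ± 0.135 in proembryo nuclei (SD, n = 3, exact permutation p = 0.1). That of ubiquitin was 5.15 ± 0.561 and 4.54 ± 0.0321 (exact permutation p = 0.4), the other way. That of GAPDH was 7.13 ± 0.356 and 7.41 ± 1.19 (exact permutation p = 0.7).

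**Figure D1:**
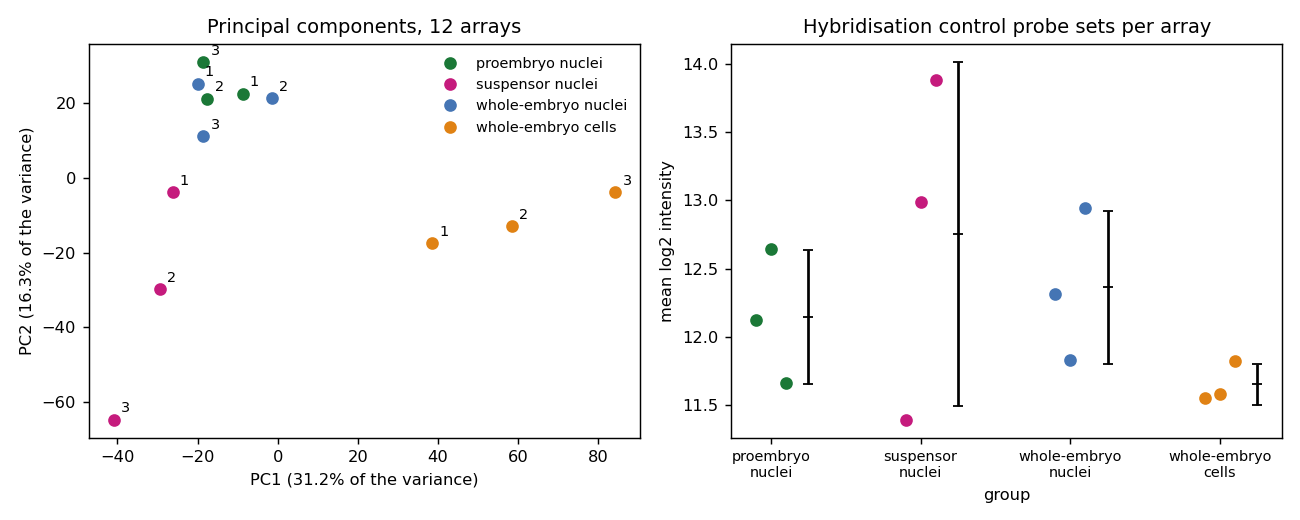
Left, the 12 arrays on the first principal components (31.2% and 16.3% of the variance), numbered by replicate and coloured by group. Right, the mean log2 intensity of the hybridisation controls on each array (points) with the group mean and SD (bars, n = 3); suspensor arrays range from 11.39 to 13.88 and cell arrays from 11.55 to 11.82.

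The central comparison asks which transcripts differ between nuclei of the suspensor and of the proembryo. PAP20, a purple acid phosphatase, was 4.26-fold higher in suspensor nuclei (log2 difference 2.09, SE 0.384, n = 3 and 3, limma adjusted p = 0.0111). RALFL18, a secreted signalling peptide, was higher by 1.56 log2 units (SE 0.382) and by 2.21 without proembryo replicate 2, which stood at 10.74 against 8.79 on both other proembryo arrays. TBL38, of a family that acetylates wall polysaccharides, was higher by 1.51 (SE 0.281), and SWEET8, a sugar transporter, by 1.49 (SE 0.364). The sucrose phosphate synthase gene ATSPS4F rose by 1.16 (SE 0.246), the carboxypeptidase-like gene scpl48 by 1.39 (SE 0.348), FIP2 by 1.25 (SE 0.261) and CCL by 1.18 (SE 0.252). On the proembryo side, ROXY1, a glutaredoxin with a role in flower development, fell by 1.64 log2 units in the suspensor (SE 0.337, adjusted p = 0.0199) and YUC4, an enzyme of auxin synthesis, fell by 1.15 (SE 0.266). The NAD(P)H dehydrogenase gene NDB4 fell by 1.43 (SE 0.299), the beta-tubulin TUB7 fell by 1.30 (SE 0.253), the histone H2B gene HTB2 fell by 1.05 (SE 0.243) and the splicing factor MAC3B fell by 0.87 (SE 0.217).

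**Figure D2:**
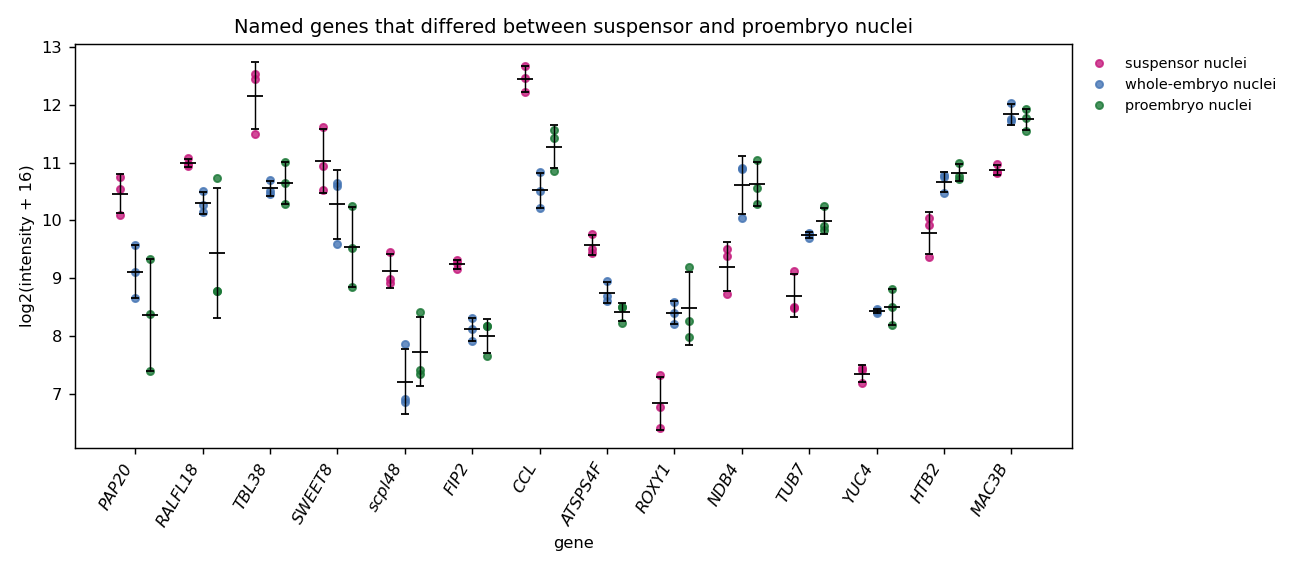
Log2(intensity + 16) of the named genes that differed between suspensor and proembryo nuclei, and of the same genes in whole-embryo nuclei; points are arrays, bars the mean and SD (n = 3). PAP20 averages 10.46 in suspensor and 8.37 in proembryo nuclei, ROXY1 6.84 and 8.48.

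In all, limma placed 260 of 12787 probe sets past the threshold, 89 higher and 171 lower in the suspensor, and 2048 (16%) had an unadjusted p under 0.05. The groups' arrays did not overlap for 2464 probe sets (19.3%, where chance gives 10%). Of the 260, 250 differed at least 2-fold and 35 at least 4-fold, and 134 had 1 gene, 14 of them with a symbol. Among genes known only by locus tag, chosen after their values were seen, AT1G47540 (2.85, SE 0.492), AT3G62480 (2.67, SE 0.33) and AT2G31945 (2.62, SE 0.345) rose most, while AT5G48350 fell by 2.91 (SE 0.374) and AT5G62440 fell by 2.13 (SE 0.278) on 1 probe set and stood at -0.89 (SE 0.293), not past the threshold, on its other. The count was 17 without the intensity trend, 62 with arrays centred on their medians, 141 with all 12 arrays in the fit, 155 with only the arrays compared, 163 with the control level as a covariate and 167 without the filter. It was 113, 118 and 85 without proembryo replicate 1, 2 and 3, and 421, 98 and 111 without suspensor replicate 1, 2 and 3. The larger number of lower calls did not hold throughout: 62 were higher and 51 lower without proembryo replicate 1, 60 and 58 without proembryo replicate 2, and 9 and 8 without the intensity trend. Of the 24 genes and loci chosen among those past the threshold, 15, 11 and 11 passed without proembryo replicate 1, 2 and 3, 21, 13 and 8 without suspensor replicate 1, 2 and 3, and 21, 18 and 21 without whole-embryo nuclei replicate 1, 2 and 3, with the direction kept for all 24. Each was chosen with no overlap between the arrays of the groups, so leaving out an array could not have reversed its direction.

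Sugar and amino acid transporters were higher as a group in suspensor nuclei, with a median log2 difference of 0.48 over 10 measured genes, 9 of them higher. The camera adjusted p was 0.0324 over 6 fixed lists and 0.054 over all 30, the latter seen before the former was computed, and with an estimated correlation the p was 0.0548 and the adjusted p 0.282. SWEET8 was the 1 member past the threshold over all probe sets, and also the 1 member adjusted over the list alone (limma adjusted p = 0.00742); SWEET7 (0.66, SE 0.296) and SWEET1 (0.52, SE 0.269) were not past it. The adjusted p over fixed lists was 0.0686 without proembryo replicate 1, 0.0741 without proembryo replicate 3, 0.0536 and 0.0737 without suspensor replicate 2 and 3, and 0.0537 without whole-embryo nuclei replicate 3. The autophagy list, built from the annotation, had a median of 0.56 over 10 genes and the same camera adjusted p over all 30 lists, 0.054. Adjusted over that list alone, 4 of its members were higher past the threshold. Between suspensor and proembryo nuclei the log2 3' to 5' ratio was 3.59 against 4.57 for actin, 5.15 against 4.54 for ubiquitin and 7.13 against 7.41 for GAPDH.

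Genes of mRNA processing and export, a list built from the annotation, were lower in suspensor nuclei, with a median of -0.47 over 23 genes, 18 of them lower (camera adjusted p = 0.0191 over all 30 lists). The p with an estimated correlation was 0.02 and the adjusted p 0.418, and fry's adjusted p was 0.0566. MAC3B alone fell past the threshold over all probe sets; Y14, an exon junction protein, differed by -0.94 (SE 0.285), and FY, of the polyadenylation machinery, by -0.82 (SE 0.261). The adjusted p was 0.0753 without suspensor replicate 1 and 0.0966, with a median of -0.31, without suspensor replicate 2. The same arrays differed in the log2 3' to 5' ratio of actin (3.59 in suspensor, 4.57 in proembryo nuclei). The ratio of ubiquitin went the other way (5.15 and 4.54, exact permutation p = 0.4). For GAPDH it was 7.13 and 7.41 (exact permutation p = 0.7).

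The other fixed lists did not pass by camera in this comparison, and adjusted over the list alone HTB2 was the 1 member past the threshold. Nuclear photosystem genes had a median of 0.40 over 7 genes (adjusted p = 0.0916), with PSBW at 0.63 (SE 0.23), LHCB4.3 at 0.54 (SE 0.31) and PSAE-1 at 0.48 (SE 0.226). Histones had a median of -0.46 over 4 genes (adjusted p = 0.109; 0.0358 with fry, which does not compare a list with other genes): HTB2 fell, and HTR12, the centromeric H3, differed by -0.76 (SE 0.486) and HON4 by -0.17 (SE 0.252). Mitochondrion-encoded genes had a median of 0.10 over 13 genes (adjusted p = 0.241), with cox1 at 0.92 (SE 0.357), ccb382 at 1.14 (SE 0.474) and nad9 at 0.76 (SE 0.325). Plastid-encoded genes had a median of 0.13 over 34 genes (adjusted p = 0.517), with rpl33 at 1.31, psaI at 1.25 and psaJ at 0.92; the median turned to -0.02 without proembryo replicate 2 and -0.29 without suspensor replicate 1. Expansins and xyloglucan endotransglucosylases had a median of 0.18 over 12 genes (adjusted p = 0.517), with XTH16 at -0.79, EXLA3 at 0.57 and EXLA1 at 0.49.

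Several regulators could be read only as single genes. BBM, a transcription factor that promotes embryo identity, differed by -1.05 (SE 0.302, adjusted p = 0.0815; 0.00289 adjusted over the list alone, where it was the 1 measured member, so that this is its unadjusted p). The seed coat gene BAN, an enzyme of tannin synthesis, stood at 0.58 (SE 0.245, adjusted p = 0.25; unadjusted p = 0.029, as the 1 measured member of its list), and the endosperm genes AGL80 and AGL62 at 0.67 (SE 0.451 and 0.564). Not past the threshold either were DME, a DNA demethylase (0.75, SE 0.378), the epidermal receptor kinases CR4 (-0.72, SE 0.395) and GSO1 (0.04, SE 0.271), the replication factor PRL (-0.46, SE 0.265) and the leaf polarity gene PHV (0.15, SE 0.752). IAA31 (-0.31) and IAA18 (-0.23), repressors of auxin response, ATHSP22.0 (0.30), the zinc finger gene STZ (-0.16) and the proteasome subunit RPN12a (0.02) were likewise not past it.

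Proembryo nuclei were then set against nuclei of the whole embryo, which hold both lineages. No probe set passed, and no gene is called different: limma gave 0 of 12787, with 402 (3.14%) at an unadjusted p under 0.05 and 1053 (8.23%) whose groups did not overlap, where chance gives 10%. The genes with the smallest p were CHLM, of chlorophyll synthesis (0.74, SE 0.237), CCL (0.76, SE 0.252) and CXE18 (1.07, SE 0.362) in one direction, and MSRA5 (-0.87, SE 0.29), ATSIK (-0.99, SE 0.373) and AAPT2 (-0.84, SE 0.318) in the other, all with an adjusted p of 1. Without proembryo replicate 2 the count was 1, the locus AT5G26270 (5.10, SE 0.302), named after its value was seen.

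Mitochondrion-encoded genes were lower as a group in proembryo than in whole-embryo nuclei, with a median of -0.42 over 13 genes, 11 of them lower and 0 past the threshold by limma (camera adjusted p = 0.00108). Its p with an estimated correlation was 0.0953, and with fry 0.174. The adjusted p was 0.0605 without proembryo replicate 1 and 0.549, with a median of -0.26, without whole-embryo nuclei replicate 1. Plastid-encoded genes (median -0.11, 34 genes), sugar and amino acid transporters (-0.09, 10), histones (-0.13, 4), photosystem genes (-0.02, 7) and expansins (0.03, 12) each had an adjusted p of 0.918, with 0 members past the threshold adjusted over the list alone. Camera's direction was up for the photosystem genes and down for the expansins, against the sign of their medians. Without proembryo replicate 3 the plastid list had a median of -0.27 and an adjusted p of 0.0321, and the histone median was 0.05; without proembryo replicate 2 the plastid median was 0.08.

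Suspensor nuclei were also set against whole-embryo nuclei. CuAO1, a copper amine oxidase, was higher in the suspensor by 2.08 log2 units (SE 0.394, n = 3 and 3, limma adjusted p = 0.0157), CCL by 1.93 (SE 0.252), scpl48 by 1.91 (SE 0.348), TBL38 by 1.60 (SE 0.281) and the carnitine transporter gene OCT1 by 1.51 (SE 0.277). With a pseudocount of 64 CuAO1 stood at 1.475. ROXY1 fell by 1.57 (SE 0.337, adjusted p = 0.0305), NDB4 fell by 1.41 (SE 0.299), YUC4 fell by 1.09 (SE 0.266), TUB7 fell by 1.05 (SE 0.253) and MAC3B fell by 0.96 (SE 0.217). The suspensor arrays are those of the comparison with the proembryo, so the recurrence of names is not independent evidence.

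In this comparison 199 of 12787 probe sets passed, 76 (38.2%) higher and the others lower in the suspensor, with 1829 (14.3%) at an unadjusted p under 0.05. The count was 9 without the intensity trend, 49 with median centring, 55 with all 12 arrays and 104 without the filter. It was 309, 57 and 92 without suspensor replicate 1, 2 and 3, and 37, 27 and 122 without whole-embryo nuclei replicate 1, 2 and 3. The share of higher calls, 38.2%, was 56.8% without whole-embryo nuclei replicate 1, 74.1% without whole-embryo nuclei replicate 2, 26.9% without suspensor replicate 1 and 88.9% without the intensity trend. It was 50.9% with all 12 arrays, and 49% both without the filter and with only the arrays compared. Of 20 genes and loci chosen among those past the threshold, 7, 7 and 14 passed without whole-embryo nuclei replicate 1, 2 and 3, and of 19 measured there, 17, 11 and 12 passed without suspensor replicate 1, 2 and 3.

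Genes of mRNA processing and export had a median of -0.34 over 23 genes (camera adjusted p = 0.0352 over all 30 lists), with MAC3B past the threshold. Estimating the correlation gave a p of 0.0244 and an adjusted p of 0.367, and fry's adjusted p was 0.0724. That list's adjusted p was 0.056 and 0.0867 without suspensor replicate 1 and 2, and 0.144 without whole-embryo nuclei replicate 2. The log2 3' to 5' ratio of actin differed between these groups too, 3.59 in suspensor and 4.48 in whole-embryo nuclei (n = 3 and 3, exact permutation p = 0.1). Ubiquitin stood at 5.15 and 4.70 (exact permutation p = 0.3) and GAPDH at 7.13 and 7.71 (exact permutation p = 0.2). Photosystem genes (median 0.31, adjusted p = 0.0501), sugar and amino acid transporters (0.37, 0.0501) and histones (-0.56, 0.0514; 0.044 with fry) were just outside the threshold, with 1 histone and 0 members of the others past it adjusted over the list alone, while mitochondrion-encoded genes (-0.19, 0.549), expansins (0.19, 0.657) and plastid-encoded genes (-0.02, 0.801) were not near it; camera's direction for the plastid genes was up. Without proembryo replicate 1 the photosystem genes and the transporters passed (both 0.0457), without suspensor replicate 1 the transporters (0.0458), without suspensor replicate 2 the photosystem genes, the transporters and the histones (each 0.0478), and without whole-embryo nuclei replicate 3 the photosystem genes (0.0399). The plastid median was -0.43 without suspensor replicate 1 (adjusted p = 0.0336), and the mitochondrial median 0.02 without whole-embryo nuclei replicate 1.

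Among the 260 probe sets that separated suspensor from proembryo nuclei, the mean of whole-embryo nuclei lay between the means of both lineages for 208 (80%, exact 95% interval 74.6 to 84.7) and nearer the proembryo for 234 (90%). Over all 12787 probe sets kept, these shares were 42% and 63.5%. The 260 were selected for a large difference between the lineages. That by itself raises the share between, so 42% is not the share to be expected of them without a mixture. No test was made. Without whole-embryo nuclei replicate 3 the share between fell to 56.2%, outside the interval of 74.6 to 84.7. That interval treats probe sets as independent and does not measure the spread between arrays.

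Cells of the whole embryo were compared with its nuclei, a contrast of cellular with nuclear RNA in which stage, fixation and extraction also differ. The expansin gene EXPA21 was 15-fold higher in cells (log2 difference 3.91, SE 0.423, n = 3 and 3, limma adjusted p = 0.000694). SK16, of the SKP1-like family, was higher by 3.52 (SE 0.42), the sucrose transporter SWEET9 by 2.81 (SE 0.363), the spermidine acyltransferase SDT by 2.68 (SE 0.567), the kinase NCRK by 2.60 (SE 0.537) and the tetraspanin TET10 by 2.53 (SE 0.319). ZW9 (2.43, SE 0.38), MPC, an imprinted gene of the endosperm (1.96, SE 0.294), the MADS-box gene AGL57 (1.78, SE 0.396) and scpl47 (1.77, SE 0.444) followed. Lower in cells were iqd33, which fell by 3.06 (SE 0.49), the defensin-like LCR69, which fell by 2.98 (SE 0.562), CCL, which fell by 2.86 (SE 0.315), and the thionin THI2.1, which fell by 2.51 (SE 0.4).

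The other named decreases were RXF26 (log2 difference -2.57, SE 0.419), scpl41 (-2.49, SE 0.527), ARL (-2.34, SE 0.412), the auxin-conjugating enzyme GH3.3 (-2.33, SE 0.582), the plantacyanin ARPN (-2.26, SE 0.401) and RALFL18 (-2.23, SE 0.271). Among loci without a symbol, chosen after their values were seen, AT3G15720 was higher in cells by 5.55 (SE 0.439) and AT4G27590 fell by 4.05 (SE 0.395). With pseudocounts of 1 and 64 AT3G15720 stood at 6.79 and 4.32, and AT4G27590 at -5.10 and -2.81. The hybridisation controls stood at 11.65 on the cell arrays and 12.36 on the nuclear arrays. Single arrays moved the fold of some named genes by over 1.5 times: without cell replicate 1 LCR69 stood at -3.83 and scpl41 at -3.18, and without cell replicate 3 GH3.3 stood at -1.56. SDT stood at 3.28 and 2.07 without whole-embryo nuclei replicate 2 and 3, the latter not past the threshold (adjusted p = 0.077). With a pseudocount of 1 NCRK stood at 4.04 and was not past it (adjusted p = 0.0832). With a pseudocount of 64 it stood at 1.39. Pseudocounts of 1 and 64 also moved SK16 (4.33 and 2.50), SDT (3.555 and 1.794) and iqd33 (-4.01 and -2.06). They moved RXF26 (-3.47 and -1.59) and scpl41 (-3.375 and -1.548) as well, and 64 moved ZW9 to 1.66.

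**Figure D3:**
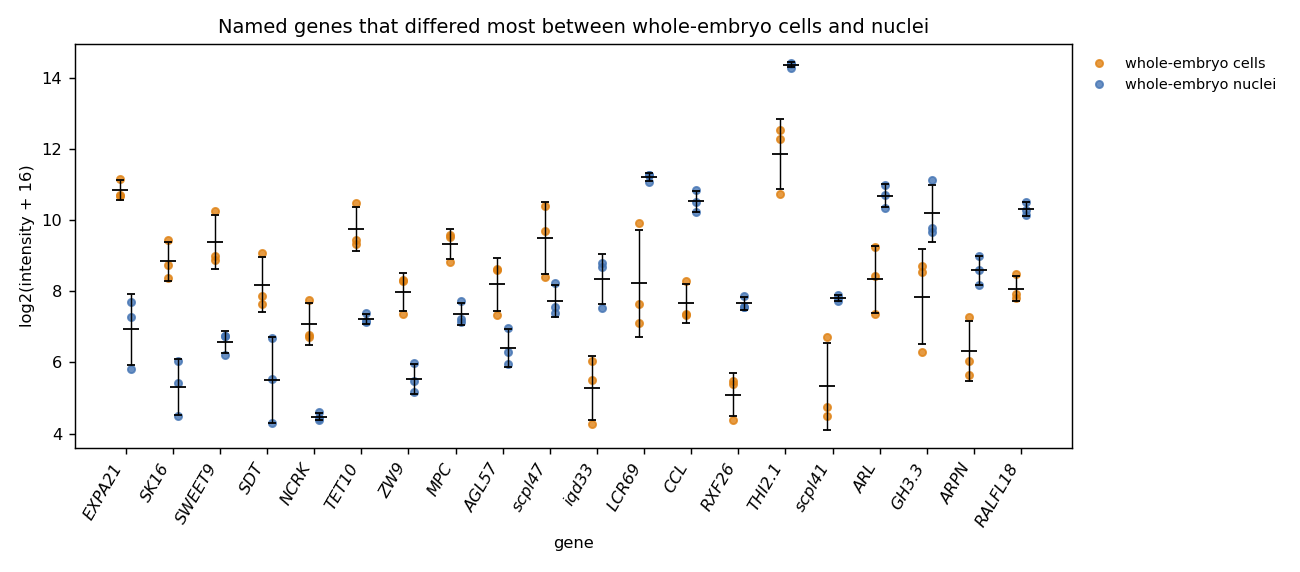
Log2(intensity + 16) of the named genes that differed most between whole-embryo cells and nuclei; points are arrays, bars the mean and SD (n = 3). EXPA21 averages 10.84 in cells and 6.94 in nuclei, THI2.1 11.85 and 14.36.

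In all 803 of 11867 probe sets passed, 322 higher and 481 lower in cells (40.1% higher), with 2832 (23.9%) at an unadjusted p under 0.05 and 3394 (28.6%) without overlap, where chance gives 10%. Of these, 773 differed at least 2-fold and 260 at least 4-fold. With median centring, which moved the median of all probe sets to 0.14, the split was 432 higher and 357 lower (54.8% higher). With the control level as a covariate 8 passed: the median size of the 803 went from 1.59 to 1.56 and the median SE from 0.327 to 0.483, with the direction kept for 803. The count was 462 without the filter, 535 with a stricter one and 3242 with array weights. It was 205, 260 and 218 without whole-embryo nuclei replicate 1, 2 and 3, 1287 without cell replicate 1 and 249 without cell replicate 2. The share of higher calls, 40.1%, was 51.2%, 53.1% and 53.7% without whole-embryo nuclei replicate 1, 2 and 3, 22.1% without cell replicate 2 and 75% of the 8 with the covariate. Of 36 genes and loci chosen among those past the threshold and measured there, 24, 29 and 22 passed without whole-embryo nuclei replicate 1, 2 and 3, and of 33, 32, 24 and 33 passed without cell replicate 1, 2 and 3.

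Mitochondrion-encoded transcripts were lower in cells than in nuclei, with a median of -1.49 over 11 genes, 5 of which fell past the threshold and 7 adjusted over the list alone (camera adjusted p = 4.69e-06). The p was 0.0877 with an estimated correlation, and the median was -2.42 with the filter at the 75th percentile and -0.95 with a pseudocount of 64. The respiratory chain gene nad1 fell by 3.60 (SE 0.388) on its brightest probe set, ccb452 fell by 2.94 (SE 0.433), nad9 fell by 2.42 (SE 0.454) and nad4L fell by 2.08 (SE 0.398). Plastid-encoded transcripts were higher in cells, with a median of 0.27 over 33 genes, 5 of which rose past the threshold and 9 adjusted over the list alone (camera adjusted p = 0.00391). That list's p was 0.235 with an estimated correlation and 0.0774 with fry. Its median lay between 0.43 and 0.48 with 1 whole-embryo nuclei array left out, and stood at 0.54 without cell replicate 3, 0.69 with the filter at the 75th percentile, 0.62 with array weights and 0.49 with the control level as a covariate. The ATP synthase gene atpE rose by 2.53 (SE 0.346), the protease gene clpP by 2.48 (SE 0.437), and the ribosomal protein genes rpl22 by 1.77 (SE 0.444) and rps19 by 1.62 (SE 0.341). With a pseudocount of 1 rpl22 was not past the threshold (adjusted p = 0.0729). With the control level as a covariate atpE stood at 1.81 and was not past it (limma adjusted p = 0.18). Between the same arrays the hybridisation controls stood at 11.65 in cells and 12.36 in nuclei, and the 25S ribosomal RNA probe set at 9514 and 22150 intensity units.

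RALF-like peptides, a list built from the annotation, were lower in cells, with a median of -0.87 over 9 genes, 4 of which fell past the threshold and 6 adjusted over the list alone (camera adjusted p = 0.000231 over all 29 lists). Estimating the correlation gave a p of 0.0109 and an adjusted p of 0.317. With the control level as a covariate the median was -0.56. The controls stood at 11.65 in cells and 12.36 in nuclei, and 25S ribosomal RNA at 9514 and 22150. Beside RALFL18, RALFL32 fell by 1.75 (SE 0.342), RALFL22 fell by 1.39 (SE 0.25) and RALFL24 was 2.49-fold lower (SE 0.254 on the log2 scale).

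**Figure D4:**
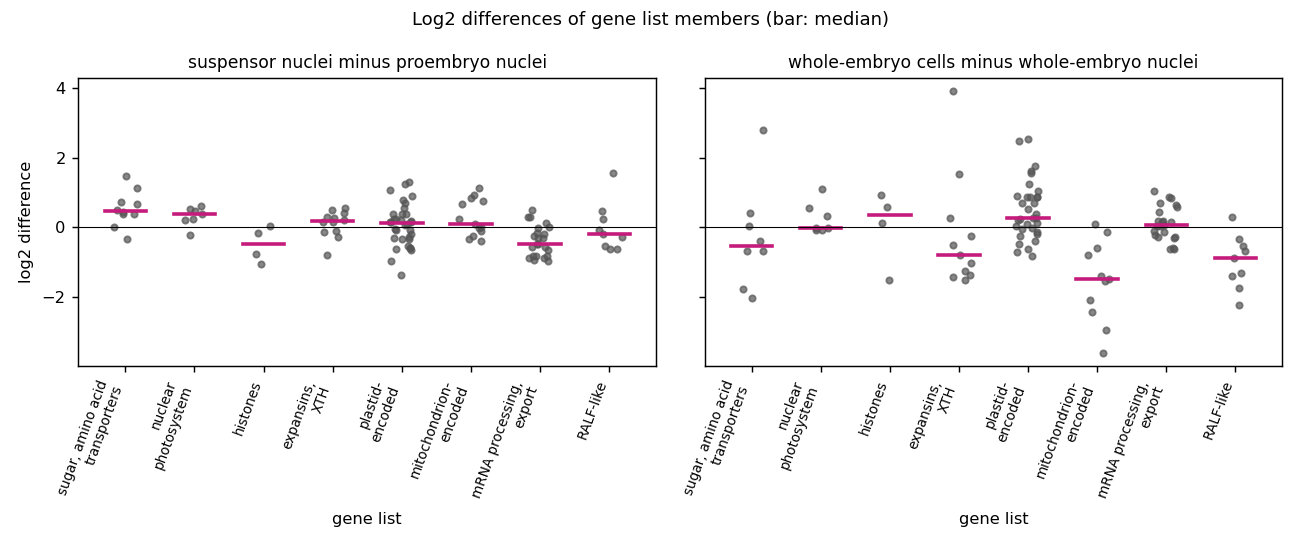
Log2 differences of the measured members of 8 gene lists, suspensor minus proembryo nuclei on the left and cells minus whole-embryo nuclei on the right; points are genes, bars list medians. Mitochondrion-encoded genes have a median of -1.49 on the right and 0.10 on the left.

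Other lists went both ways or did not pass by camera. Of 11 expansins and xyloglucan endotransglucosylases (median -0.79, adjusted p = 0.229), EXPA21 rose, XTH16 fell by 1.52 (SE 0.283), AT4G30380 fell by 1.42 (SE 0.374), and XTH19 stood at 1.54 (SE 0.438); adjusted over the list alone, 2 members were higher and 5 lower past the threshold, and without cell replicate 1 the list had a median of -1.14 and an adjusted p of 0.0405. Of 8 sugar and amino acid transporters (median -0.54, adjusted p = 0.259; 0.043 with fry), SWEET9 rose and SWEET4 fell by 2.02 (SE 0.254), with SWEET10 at -1.78 (SE 0.562; -1.08 without cell replicate 3, and -2.47, past the threshold, without cell replicate 1) and SWEET1 at -0.69 (SE 0.246); adjusted over the list alone, 1 was higher and 4 lower past the threshold. Histones (median 0.36, 4 genes, adjusted p = 0.475) held HIS1-3 at -1.50 (SE 0.466), HTR12 at 0.94 (SE 0.312), both past the threshold adjusted over the list alone, and HTB2 at 0.59 (SE 0.271). Photosystem genes (median -0.00489, 7 genes, adjusted p = 0.319, camera direction up) held PSAN at 1.10, PSBY at 0.57 and LHCB4.1 at 0.33, with 0 past the threshold adjusted over the list alone; the median was 0.57 without cell replicate 3 (adjusted p = 0.00534) and -0.15 without cell replicate 1.

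Single regulators did not pass in cells against nuclei. BBM stood at 0.74 (SE 0.391), PHV at 0.83 (SE 0.771), GSO1 at 0.46 (SE 0.312), CR4 at -0.12 (SE 0.265), PRL at -0.10 (SE 0.291) and DME at -0.07 (SE 0.287). AGL80 stood at 0.29 (SE 0.248), BAN at 0.57 (SE 0.404), RPN12a at 0.59 (SE 0.284), IAA18 at 0.36 (SE 0.271), IAA31 at -0.39 (SE 0.388) and ATHSP22.0 at -0.81 (SE 0.333, adjusted p = 0.168; unadjusted p = 0.0323, as the 1 measured member of its list).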

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

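The fit with the hybridisation control level as a covariate was chosen after seeing the data; the other alternatives were set before. The alternative scale for values already on a log scale was not run because the values are linear, and fitting only the groups compared is what cells against nuclei already uses. Under every alternative run, the genes and loci chosen among those past the threshold (24, 20 and 41 in suspensor against proembryo, suspensor against whole-embryo nuclei, and cells against nuclei) kept their direction wherever they were measured, while fewer stayed past the threshold: without the intensity trend 4 of 24, 4 of 20 and 39 of 41, with median centring 9, 13 and 40, and with the covariate 16, 18 and 4. All but the list members in cells against nuclei were chosen with no overlap between the arrays of the groups. For those chosen so, only normalization between arrays and the covariate could have reversed the direction. Median centring moved the median of all probe sets tested to -0.09, -0.11 and 0.14 in these comparisons. Where a count or call changed, the cause was not tested, except that without the filter more probe sets share the adjustment and that leaving out an array leaves fewer. How far dim probe sets lie above background is unknown, which limits what can be said of them.

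Of 260 probe sets in suspensor against proembryo nuclei, the count was 167 without the filter, 62 with median centring, 141 with all 12 arrays, 155 with only the groups compared, 17 without the intensity trend and 163 with the covariate, and between 85 and 421 with 1 array left out. Proembryo against whole-embryo nuclei gave 0 by limma in every alternative (402 at an unadjusted p under 0.05 in the reported fit), and 0 to 1 with 1 array left out. For suspensor against whole-embryo nuclei the 199 became 104 without the filter, 49 with median centring, 55 with all 12 arrays and 9 without the trend, and between 27 and 309 with 1 array left out. The 803 of cells against nuclei became 462 without the filter, 535 with the filter at the 75th percentile, 3242 with array weights and 8 with the covariate, and between 205 and 1287 with 1 array left out. The share of probe sets with whole-embryo nuclei between both lineages was 56.2% to 87.1% with 1 array left out.

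With the replicate block, 285, 0, 203 and 774 probe sets passed in the order just given, and the numbers were not taken as pairing the samples: 0 pairs of same-numbered arrays had deviations correlated over 0.1, and 1, 0, 4 and 2 of 6 arrays correlated best with their own number. The paired fit gave 7 fixed-list calls in place of 4, the added ones being photosystem genes, transporters and histones in suspensor against whole-embryo nuclei (each with an adjusted p of 0.0461).

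The number of fixed-list calls, 4, was 0 with an estimated correlation, 7 with a pseudocount of 1, 2 with the stricter filter and 8 with quantile normalization. It was 5 with fry, which added histones in both suspensor comparisons and transporters in cells against nuclei. Fry did not call the mitochondrial list in proembryo against whole-embryo nuclei or the plastid list in cells against nuclei. The transporter list in suspensor against proembryo nuclei had an adjusted p of 0.103 without the filter, 0.121 with the stricter filter and 0.0621 with only the groups compared, and the mitochondrial list in proembryo against whole-embryo nuclei had 0.0535 with the stricter filter. In suspensor against proembryo nuclei the photosystem genes passed with quantile normalization (0.0275) and with the covariate (0.029), and the plastid genes with the covariate (0.0204). With array weights the photosystem genes and the transporters passed in suspensor against whole-embryo nuclei (camera adjusted p = 0.0449 for both). The mRNA processing list had 0.136 and 0.113 with the stricter filter in suspensor against proembryo and whole-embryo nuclei.

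Reversals concerned values not past the threshold, save the plastid list in suspensor against whole-embryo nuclei without suspensor replicate 1 (-0.425), and their cause was not tested; for a list, a reversal is a turn of camera's direction. In suspensor against proembryo nuclei the plastid median was -0.306 with the stricter filter, RPN12a -0.081 with median centring and -0.094 with array weights, and GSO1 -0.064, -0.094 and, with the covariate, -0.0062. With 1 array left out, PHV ranged from -0.40 to 0.80, ATHSP22.0 from -0.39 to 0.67, RPN12a from -0.22 to 0.23, GSO1 from -0.21 to 0.23, STZ from -0.38 to 0.11 and the plastid median from -0.292 to 0.29. In proembryo against whole-embryo nuclei the plastid median was 0.0762 without the filter and -0.0121 with array weights, and the expansin median 0.0283 with all 12 arrays, 0.0529 with array weights and 0.0459 with the covariate; with 1 array left out the plastid median ranged from -0.271 to 0.0849, histones from -0.143 to 0.0455, photosystem genes from -0.174 to 0.0973 and expansins from -0.0366 to 0.0262. In suspensor against whole-embryo nuclei the plastid median was -0.217 with the stricter filter and ranged from -0.425 to 0.251 with 1 array left out, mitochondrial genes from -0.513 to 0.0328 and expansins from 0.0282 to 0.278. In cells against nuclei the expansin median was -0.259 with the stricter filter, PRL 0.035, CR4 0.0099 and DME 0.056 with median centring, and CR4 0.063 and DME 0.061 with the covariate; with 1 array left out PHV ranged from -0.37 to 1.62, IAA31 from -0.73 to 0.10, PRL from -0.35 to 0.08, LHCB4.1 from -0.15 to 0.87, DME from -0.31 to 0.091 and the photosystem median from -0.149 to 0.569.

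List members were followed as single genes only in suspensor against proembryo nuclei and cells against nuclei, a reading of the rule settled after these reversals had been seen. Of the 32 members in proembryo against whole-embryo nuclei 0 passed, and 12 of 675 values under alternatives, from 8 members, reversed; in suspensor against whole-embryo nuclei 0 of 32 passed and 6 of 685 values, from 3 members, reversed, with 0 reversed values past the threshold in either (limma).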

Other observations

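The tests on the plastid list and the use of the control level as a covariate were chosen after the results they bear on were seen; before the tests on endosperm, seed coat and egg cell genes, results of some of these lists and the values of MPC and AGL57 had been seen, though not the medians tested.

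Many transcripts of cytosolic ribosomal proteins had lower values in suspensor than in proembryo nuclei. With an estimated correlation the class was not called after adjustment. The ribosomal P protein loci AT5G47700 (-1.92) and AT2G27710 (-1.75) drew attention to the class, and the remaining loci, recalled from memory after these were seen, were then tested: of 100 measured, 94 were lower, with a median of -0.68, and 17 fell past the threshold by limma against 0 that rose. With an estimated correlation of 0.27, camera gave an unadjusted p of 0.0263, and adjusted together with the lists tested in this comparison the p was 0.384. Of the signs of RNA quality, the log2 ratio of 3' to 5' actin signal was 3.34 to 3.86 on the suspensor arrays and 4.46 to 4.72 on the proembryo arrays. That of ubiquitin averaged 5.15 and 4.54 (exact permutation p = 0.4), and that of GAPDH 7.13 and 7.41 (exact permutation p = 0.7). Of the 175 remaining loci, 37 have a name in the annotation and 30 of those names are ribosomal. The 1 locus named as a kinase was left out, in a rule revised after the p had been seen, so 174 were used. With it included the measured genes and the p were the same. A lower level of the class in the suspensor may underlie the pattern, but RNA quality and other technical explanations were not tested for it and stay open.

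The difference between suspensor and proembryo nuclei could come from less labelled RNA on some suspensor arrays, whose hybridisation controls reached 13.88. Suspensor replicate 1 has the lowest control level of the nuclear arrays, 11.39. Of the 421 probe sets called without it, 86% have it on the called side of the whole-embryo mean, against 58.9% of all probe sets. The exact 95% interval, 82.3 to 89.2, treats probe sets of 1 array as independent and does not measure the spread between samples. The share argues against labelling as the whole cause, although it rests on 1 array. With the control level as a covariate 163 probe sets passed, 151 of them among the 260. The median size of the 260 went from 1.39 to 1.30, with the direction kept for 260. Their median SE went from 0.294 to 0.289, so it did not grow. Fitting only the arrays compared, without the covariate, kept 150 of the 260. The lower count with the covariate therefore does not by itself point to labelling. Labelling stays open as a part of the difference. RNA of endosperm or seed coat in the sort stays open. The median over 8 measured genes of these tissues and of flavonoid synthesis was 0.27 (bootstrap interval -0.397 to 0.668). The endosperm genes AGL80 and AGL62 (both 0.67) and the seed coat gene BAN (0.58) were higher in the suspensor, not past the threshold. Of the flavonoid genes, UGT78D2 (0.40) and CHI (0.14) were higher, and CHIL (-0.24), DFR (-0.40) and UGT78D1 (-0.53) lower. Over the nuclear arrays BAN averaged 12.86 and DFR 11.16 log2 units, against 10.46 for PAP20 in suspensor nuclei. Signal of a seed coat gene was thus strong in these nuclei, and its source was not tested. A sort by the marker should remove nuclei of these tissues but not free RNA, which was not tested either. The difference of lineage itself stays open, as untested.

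The difference between cells and nuclei could likewise come from labelling, since the control levels differ (11.65 and 12.36). With the level as a covariate 8 probe sets passed. The median size of the 803 went only from 1.59 to 1.56, with the direction kept for 803, while the median SE rose from 0.327 to 0.483. The loss of calls as a whole is therefore no evidence for labelling. Some differences shrank more: SDT went from 2.68 to 1.499, SK16 from 3.52 to 2.78, iqd33 from -3.06 to -2.14, AGL57 from 1.78 to 1.18 and the plastid gene atpE from 2.53 to 1.81. The locus AT5G22810 went the other way, from 4.32 to 5.72. Labelling stays open as part of the difference in the genes whose difference shrank so. Cell replicate 3 and whole-embryo nuclei replicate 2 have nearly equal levels (11.82 each). Of 364 probe sets called from the other 4 arrays, 92% differ the same way between them (exact 95% interval 88.8 to 94.6). The interval treats probe sets as independent and does not measure the spread between samples. The same share over all probe sets was not computed, so how far 92% exceeds it is unknown. With that limit the share argues against labelling as the whole cause, although it rests on 1 array of each group. Endosperm RNA in embryos squeezed out by hand stays open: AGL80 and EC1.5, the 2 measured genes of the lists fixed for it, had a median of -0.26 (bootstrap interval -0.814 to 0.292), and the bound of 0.5 set beforehand was met but is no test here, because a bootstrap of 2 genes cannot leave their own range. MPC, an imprinted endosperm gene outside those lists whose value was known before, was higher in cells by 1.96 (limma adjusted p = 0.0036), the direction that endosperm RNA would give, and stage, fixation and extraction stay open too, as untested.

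Mitochondrion-encoded transcripts were lower in cells (median -1.49) and could reflect organelles that came along with the sorted nuclei. If organelles of both kinds had done so and nothing else differed, plastid-encoded transcripts would be lower in cells too. Their median was 0.27 over 33 genes, a value known before this test was chosen. Its bootstrap interval, 0.11 to 0.875, treats genes as independent. Stage, fixation and extraction differ as well and could move plastid-encoded transcripts, so organelles of both kinds are not excluded. Mitochondria carried along without plastids, the later stage of the cells and the different extraction stay open.

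Each comparison's 6 arrays can be split into equal groups in 10 ways, which cannot give a share under 0.05. For suspensor against proembryo nuclei the real split gave 260 probe sets and the highest other 4, for suspensor against whole-embryo nuclei 199 and 0, and for cells against nuclei 803 and 0, so that 1 split reached the real count in each. For proembryo against whole-embryo nuclei the real split gave 0 by limma, with 402 at an unadjusted p under 0.05, and the highest other 1; no split can give fewer than 0, so the count of splits tests nothing there.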
